A study of Homo sapiens with 6 samples.

How the data were processed

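Gene expression was measured by RNA sequencing in SUM159 cells, an established human triple-negative breast cancer line with mesenchymal features. The groups were 3 libraries from cells carrying the empty pLVX lentiviral vector, called control, and 3 libraries from stable cells overexpressing POGK, called POGK cells. Per the labels' protocols, total RNA was depleted of ribosomal RNA before the libraries were made, and the reads were aligned to the human genome build hg38. The submitters' processing notes list Trimmomatic, STAR, SAMtools, deepTools and featureCounts, with no versions. The gene annotation and the strand setting used for counting are not given in the sources used here.

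The deposited table held raw read counts per Ensembl gene for the 6 libraries, with 18398 genes, and per the file headers each count column belonged to 1 library. The lowest total over the 6 libraries was 21, and genes with fewer reads are not analysed here. The authors also deposited a signal column per library, which from its values is the count divided by 1 size factor per library. Per the file headers, the deposited table further held the log2 fold change of POGK over control with its standard error, a test score, and a p-value with its adjusted p-value. The tool that made these columns is not stated. They were used only where the authors' deposited table is named, and all tests were run on the counts as deposited. Each of the 18398 genes was in the table under an Ensembl identifier, and 82 genes had no symbol. Biotype, position, exon length and GC content came from GENCODE release 44, which uses the same build, and 18264 of the identifiers matched it.

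Total counts ran from 27645789 to 33689230 per library. The 6 libraries were grouped by their labels. The labels name no batch and do not say that replicates are separate cultures. Pairs of libraries of 1 group were compared gene by gene with a chi-square statistic on genes with at least 20 counts. Its value per gene was 1.36 to 2.62 between POGK libraries and 22.5 to 49.7 between control libraries. No pair differed by as little as sampling noise, and all 6 were kept as separate samples. Exceeding sampling noise does not show that libraries came from separate cultures, so the POGK libraries may be technical repeats. The main test described below fitted the same spread per gene to both groups. The wide control spread, more than counting error, was therefore pooled with the narrow POGK spread, and the p-values assume that the groups spread equally.

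The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with robust estimation, TMM scaling, edgeR's default filter on low counts and Benjamini-Hochberg adjustment over the 15889 genes tested. A gene was called at an adjusted p below 0.05. Standard errors of log2 fold changes were derived from the test's F statistic. CPM values, which are counts scaled to library size, used TMM-scaled library sizes and are given as mean ± SD over 3 libraries. A set of 39 gene lists was fixed beforehand, covering ribosomes and their assembly, translation, the cell cycle, metabolism, stress responses, cell state and markers of other cells. Each list with at least 5 tested genes was tested with camera (limma 3.58.1) on voom log2 values with a preset correlation between genes of 0.01, adjusted over the lists. Camera compares a list with all other genes. The correlation was also estimated per list, camera was run on ranks, and fry was run, which asks only whether a list's own genes move. Shares of counts were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

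The rule for named genes was fixed at the same time. It took POGK, then the 10 protein-coding genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean of at least 1 CPM over all 6 libraries and no overlap between the groups. It then took the 3 members with the smallest adjusted p of the lists of cytosolic ribosomal proteins, ribosome biogenesis factors and RNA polymerase I machinery, of each list called by camera, and of the 8 lists of at least 10 tested genes with the largest share of called members. A gene taken by this rule is not reported here. Genes outside this rule are named as chosen after their values were seen.

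The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2-style size factors in edgeR, library size alone, no filter, a filter of 1 CPM in 3 libraries, protein-coding genes only, the replicate number as a block, and each library left out in turn. Removal of lowess trends in GC content and exon length per library, leaving out mitochondrial genes and thinning all libraries to 1 depth were added after seeing the data. The scripts were tested on simulated counts for the comparison of POGK with control cells, drawn from the real means, dispersions and library sizes with 200 changed genes. Over 15566 genes, edgeR recovered 81.8% of the genes changed 2-fold and 100% of those changed 4-fold, with 13 unchanged genes called. The simulated groups had equal spread and few changed genes, balanced in direction. The real groups spread unequally and most genes were called, so these rates need not hold for the data. With a GC trend added to the simulation, 5480 of the unchanged genes were called over 15554 genes tested, and 16 after the trend was removed. Figures were drawn with matplotlib 3.10.9.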

Results

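SUM159 cells with the empty vector (3 libraries) and SUM159 cells stably overexpressing POGK (3 libraries) were compared by RNA sequencing. POGK is a protein with a KRAB domain, a domain known from repressors of transcription, and it derives from a pogo-like DNA transposon. The stated purpose was to identify genes regulated by POGK, and the series title ties POGK to restricted ribosome biogenesis. The control libraries held 28099173, 32680707 and 30856248 counts and the POGK libraries 33689230, 33681633 and 27645789. The labels do not say that replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

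POGK itself (ENSG00000143157; hg38 chromosome 1, 166839447 to 166856359, plus strand) rose 11.1-fold, from 69.0 ± 7.58 CPM in control cells to 768 ± 22.02 CPM in POGK cells (SD, n = 3 each). Its raw counts were 1555, 2423 and 1987 in the control libraries against 26565, 28258 and 23128 in the POGK libraries. The log2 fold change was 3.48 with a standard error of 0.10, at an edgeR adjusted p of 3.56e-07. In the authors' deposited table it was 3.48 with a standard error of 0.12. Reads from the introduced copy and from the cells' own gene cannot be separated in these counts.

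Of 15889 genes tested, 5202 were higher and 5285 lower in POGK cells at an edgeR adjusted p below 0.05, which is 66.0% of the genes. At least 2-fold differences were found for 1522 of the higher and 2017 of the lower genes. The groups did not overlap for 73.7% of the genes, where chance gives 10% for 3 against 3 libraries. Called genes split 49.6% higher, and with library size alone as scaling the split was 6575 higher and 3925 lower, or 62.6% higher. That scaling moved the median of all genes to 0.19 on the log2 scale, so all directions here are relative to the TMM scale. The authors' deposited table had 5326 higher and 5529 lower genes at the same threshold, and 10104 genes were called in both analyses, each in the same direction.

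**Figure D1:**
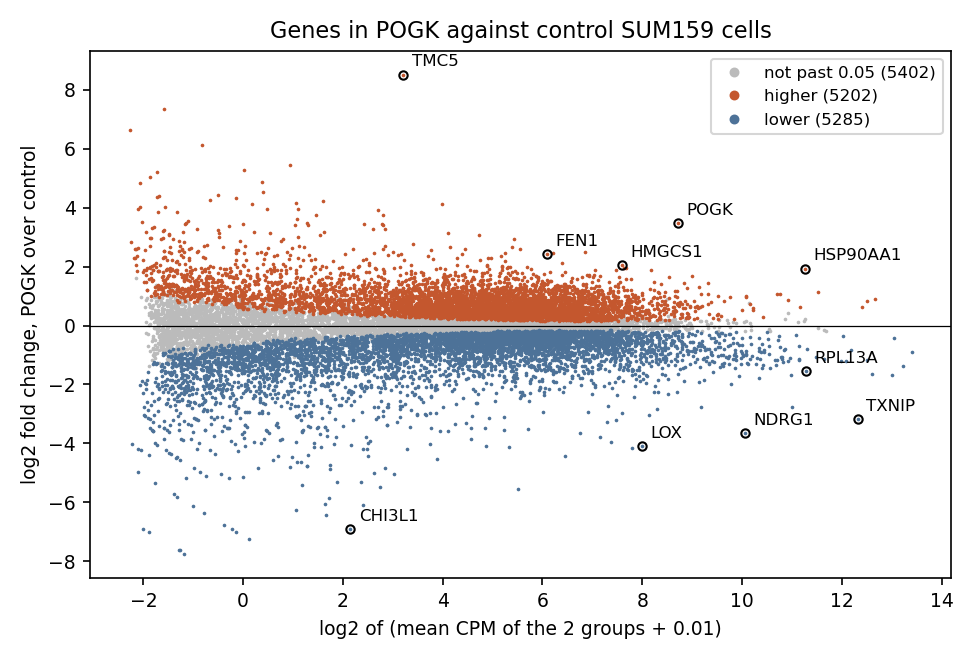
Log2 fold change of POGK over control cells against the log2 of the mean CPM of the groups plus 0.01, with 1 point per gene tested. Orange points are the 5202 genes called higher and blue points the 5285 called lower at an edgeR adjusted p below 0.05, and circles mark named genes such as POGK at 3.48.

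The genes with the largest increases had control means of at most 0.95 CPM, that of MAGEA1. TMC5, a member of the transmembrane channel-like family, had 0, 4 and 0 counts in the control libraries and 636, 692 and 550 in the POGK libraries, or 18.5 ± 0.68 CPM in POGK cells. RASGRP3, an activator of RAS proteins, rose from 0.79 ± 0.26 to 12.2 ± 1.34 CPM. MAGEA1, a cancer-testis antigen, rose from 0.95 ± 0.32 to 12.9 ± 0.59 CPM. The other genes with the largest increases were MOBP, FER1L6, ACTL8, RGS4, NPFFR2, PABPC5 and LCP2, with log2 fold changes from 3.48 for LCP2 to 4.52 for MOBP. Without control replicate 2, which held 14 of the control counts of ACTL8 and 10 of those of RGS4, these were 5.37 for ACTL8 and 5.07 for RGS4 in place of 4.15 and 3.97. These 7 genes reached between 2.51 CPM for MOBP and 5.76 CPM for FER1L6 in POGK cells. All 10 passed the edgeR test, and the weakest was ACTL8 at an adjusted p of 8.27e-05.

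Among the largest decreases, KDR, the gene of VEGF receptor 2, fell from 15.7 ± 3.21 to 0.48 ± 0.11 CPM, and GADD45G, a growth arrest gene, fell from 13.1 ± 7.20 to 0.28 ± 0.10 CPM. CHI3L1, a secreted chitinase-like protein, fell from 8.79 ± 4.14 to 0.07 ± 0.04 CPM. VCAM1, GULP1, CASP14, CCND2 and PRTN3 fell from control means between 4.12 CPM for PRTN3 and 7.15 CPM for GULP1 to at most 0.18 CPM for GULP1. LRRTM4 had 180 counts over the control libraries and 1 over the POGK libraries, a ratio of 213 with a 95% exact interval from 37.7 to 8459 that covers counting error only, with the 1 count in POGK replicate 1. These genes passed the edgeR test, and the weakest was GADD45G at an adjusted p of 7.09e-05.

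The parts of the ribosome and the factors that build it moved apart. Of 79 cytosolic ribosomal protein genes, 76 fell, none rose and 3 did not pass, and the counts were the same adjusted over the list alone. Their median log2 fold change was -1.01 with quartiles at -1.15 and -0.84. RPL13A fell from 3708 ± 549 to 1264 ± 26.5 CPM, and RPL12 and RPL37 had log2 fold changes of -1.44 and -1.43. These genes took 9.17 ± 0.85% of all counts in control cells and 5.09 ± 0.07% in POGK cells (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Ribosomal protein mRNAs share sequence with many processed pseudogenes, so single members are uncertain where reads could be split. Camera called the list lower at an adjusted p of 5.67e-20, and the adjusted p was 0.54 with an estimated correlation.

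Host genes of small nucleolar RNAs, many of which carry the same kind of translation-regulated start as ribosomal protein mRNAs, also fell: 23 of 32 were lower and 4 higher, with a median of -0.996. SNHG7 fell 4.32-fold from 108 ± 15.3 CPM, ZFAS1 4.44-fold and EPB41L4A-AS1 5.16-fold. ZFAS1 and EPB41L4A-AS1 have antisense or neighbouring partners whose reads may be mixed in, because the strand setting is not known. The camera adjusted p was 3.78e-05, and 0.54 was the adjusted p with an estimated correlation.

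Of 146 ribosome biogenesis factors, 114 rose, 10 fell and 22 did not pass (115 and 12 adjusted over the list alone), with a median log2 fold change of 0.67. EXOSC9, a subunit of the RNA exosome, rose from 38.9 ± 4.23 to 84.5 ± 2.94 CPM. The 2 members with the smallest adjusted p went the other way: NOP53, a nucleolar assembly factor of the large subunit, fell from 333 ± 44.5 to 113 ± 1.95 CPM, and RIOK3, a kinase of small-subunit maturation, fell 2.22-fold. NCL, the gene of nucleolin, chosen after its values were seen, rose from 735 ± 147 to 1429 ± 19.98 CPM. FBL, the gene of fibrillarin, and NPM1, of nucleophosmin, were likewise chosen after their values were seen. FBL had a log2 fold change of -0.15 and did not pass at an edgeR adjusted p of 0.161, and it was 0.05 with library size alone and passed at -0.23 without control replicate 3. NPM1 fell with a log2 fold change of -0.31 at an edgeR adjusted p of 0.0205, but did not pass with library size alone, at -0.11, or without any 1 of the POGK replicates, at adjusted p-values from 0.0766 to 0.0947. The number of list members that fell was 6 without POGK replicate 1 or 2 and 5 with library size alone. Camera called the list higher at an adjusted p of 7.42e-11, with an adjusted p = 0.54 with an estimated correlation.

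Of 20 genes of the RNA polymerase I machinery, which makes the large rRNA precursor, 12 rose and 3 fell. TAF1D and POLR1D fell, with log2 fold changes of -1.03 for each, and POLR2K, a subunit shared by the nuclear RNA polymerases, rose with 0.80. POLR1A, the largest subunit, and UBTF, which binds rRNA genes, were chosen after their values were seen and rose 2.30-fold and 2.27-fold. Their control levels were uneven and highest in control replicate 2, at 24.0, 48.5 and 32.3 CPM for POLR1A and 43.0, 88.2 and 61.1 CPM for UBTF. The means in POGK cells were 80.6 and 146 CPM. The list was not called by camera, at an adjusted p of 0.068, but was called at 0.0285 without control replicate 2 and at 0.0456 without a filter on low counts, in a camera range of 0.0285 to 0.543 over all alternatives. Of 23 RNA polymerase III genes, 17 rose and 3 fell, among them POLR3G with a rise of 3.81-fold, GTF3C6 with a rise of 3.24-fold and BRF2 with a fall from 17.6 ± 2.38 to 8.82 ± 0.24 CPM. This list had a camera adjusted p of 0.0027, and 0.54 was the adjusted p with an estimated correlation.

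Aminoacyl-tRNA synthetases of the cytosol rose in 15 of 23 cases and fell in 2 (1 when any POGK replicate was left out). The list's mean lay at 0.32 on the log2 scale in control replicate 2, against -0.21 and -0.11 in the other control libraries and 0.54 in POGK cells. VARS1 reached 239 ± 0.94 CPM from 121 ± 25.9 CPM. HARS1 rose 1.51-fold and QARS1 had a log2 fold change of -0.79. The camera adjusted p was 0.0044, or an adjusted p = 0.56 with an estimated correlation. Translation initiation and elongation factors were mixed, with 17 of 41 higher and 16 lower, and their median of -0.13 became 0.07 with library size alone and lay between -0.19 (without control replicate 3) and -0.05 (without control replicate 1) with 1 library left out, and at -0.06 without control replicate 2. The list of MYC-family regulators and MYC-responsive genes had 15 of 29 higher and 8 lower and was not called, at a camera adjusted p of 0.12. MYC itself, chosen after its values were seen, fell from 592 ± 91.2 to 401 ± 7.03 CPM at an edgeR adjusted p of 0.0019.

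**Figure D2:**
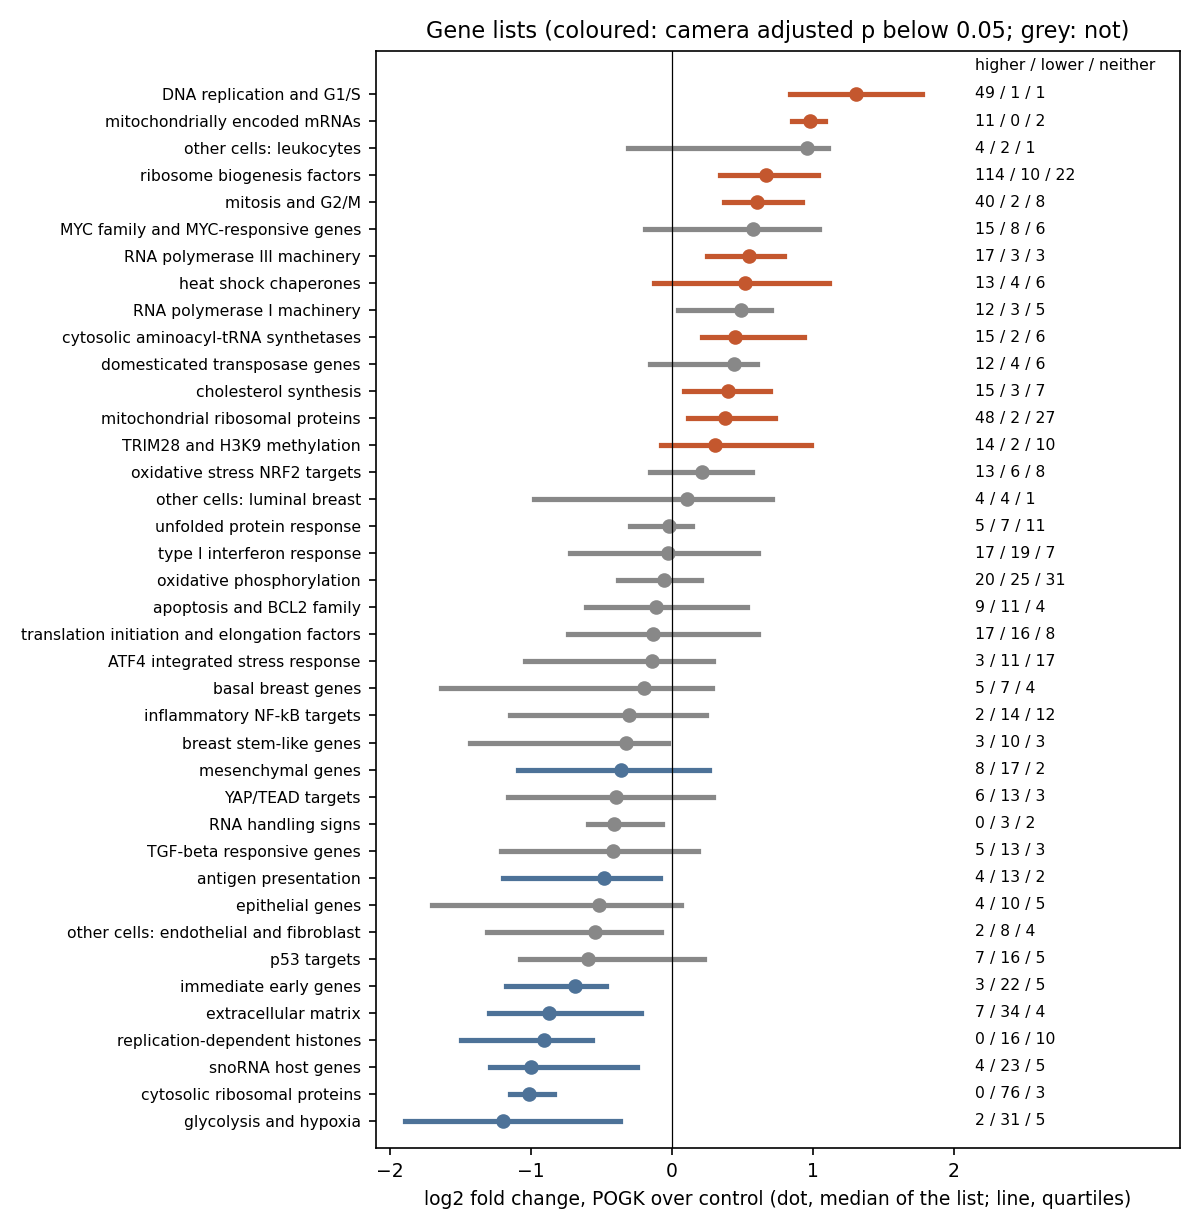
Median log2 fold change (dot) and quartiles (line) of POGK over control cells for each of the 39 gene lists, with the numbers of genes higher, lower and neither at the right. Coloured lists had a camera adjusted p below 0.05, from a median of 1.31 for DNA replication to -1.20 for glycolysis and hypoxia.

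Genes of DNA replication and the G1/S transition rose almost throughout: 49 of 51 were higher, 1 was lower (0 when any POGK replicate was left out) and 1 did not pass, with a median log2 fold change of 1.31. FEN1, the flap endonuclease of Okazaki fragment processing, rose from 21.5 ± 3.10 to 115 ± 2.14 CPM, and CCNE2, the gene of cyclin E2, rose 3.78-fold. SLBP, which binds histone mRNAs, rose 1.82-fold. Of 50 genes of mitosis, 40 rose and 2 fell (41 and 2 adjusted over the list alone; 1 fell when any library other than control replicate 2 was left out), among them SPC25, MAD2L1 and ANLN with rises of 2.51-fold, 1.71-fold and 1.66-fold. Camera gave adjusted p-values of 9.67e-15 for replication and 2.44e-08 for mitosis, and the adjusted p was 0.54 with an estimated correlation for both.

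Histone genes went the other way. Of 26 tested replication-dependent histone genes, 16 fell, none rose and 10 did not pass. H1-2 fell from 95.9 ± 42.5 to 8.47 ± 0.46 CPM, H2BC5 fell 7.31-fold and H2AC6 fell 2.65-fold. These genes have near-identical copies, so single members are uncertain, and their control levels were uneven, at 143, 84.4 and 60.2 CPM for H1-2. Counts were made per gene and do not separate transcript forms. H2BC5 and H2AC6 are annotated over long spans, 26158122 to 26171349 and 26124145 to 26139116 on chromosome 6. Whether the histone mRNAs made during DNA replication themselves fell is therefore not known. For the histones the camera adjusted p was 0.0023, or an adjusted p = 0.54 with an estimated correlation. Of 26 genes in the list of TRIM28, the corepressor that KRAB domains recruit, and of H3K9 methylation, 14 rose and 2 fell. Without control replicate 1 or 2, 4 fell. The histone methyltransferase genes SUV39H1 and SUV39H2 rose 3.12-fold and 2.56-fold and UHRF1 rose 3.92-fold, while TRIM28, chosen after its values were seen, rose 1.25-fold. Camera gave an adjusted p of 0.023 here, or an adjusted p = 0.54 with an estimated correlation.

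Glycolysis and hypoxia genes fell in 31 of 38 cases and rose in 2 (4 without control replicate 1, 1 without any other library), with a median log2 fold change of -1.20. NDRG1, induced by low oxygen, fell from 1978 ± 549 to 157 ± 6.08 CPM, ADM, the gene of adrenomedullin, fell from 311 ± 101 to 20.1 ± 1.21 CPM, and VEGFA fell 2.74-fold. Among genes chosen after their values were seen, TXNIP, a glucose-responsive inhibitor of thioredoxin, fell from 9231 ± 2245 to 1014 ± 116 CPM. Of 30 immediate early genes, 22 fell and 3 rose (23 and 3 adjusted over the list alone), including KLF6 with a fall of 4.82-fold, DUSP1 with a fall of 3.70-fold and DUSP4 with a fall of 2.35-fold. Camera gave adjusted p-values of 3.24e-08 for glycolysis and hypoxia and 2.10e-04 for immediate early genes, and the adjusted p was 0.54 with an estimated correlation for both.

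Of the 13 mRNAs encoded by mitochondrial DNA, 11 rose and 2 did not pass, with a median log2 fold change of 0.98. MT-ND4, a subunit of respiratory complex I, rose from 4565 ± 1455 to 8499 ± 464 CPM, MT-ND4L, which overlaps it, rose 1.98-fold, and MT-ND6 rose 3.97-fold. These mRNAs took 1.79 ± 0.69% of counts in control cells and 3.71 ± 0.15% in POGK cells (SD, n = 3 each; exact permutation p = 0.1), and control replicate 1 was lowest at 1.03%. Without POGK replicate 1 the number that rose was 6 and without POGK replicate 3 it was 7. MT-ND6 had 141, 549 and 615 counts in the control libraries, and its log2 fold change lay between 1.62 and 2.31 over the alternatives. It lies on the minus strand, so reads of the other strand may be mixed in, because the strand setting is not known. Nuclear genes of mitochondrial ribosomal proteins rose in 48 of 77 cases and fell in 2 (47 and 2 adjusted over the list alone; 4 fell without control replicate 3 and 1 when any POGK replicate was left out), with MRPL1, MRPS7 and MRPL35 up 2.09-fold, 1.98-fold and 1.79-fold. Camera gave adjusted p-values of 0.0044 for the mitochondrial mRNAs and 1.96e-06 for these ribosomal proteins, against an adjusted p of 0.56 and 0.54 with an estimated correlation. Nuclear genes of oxidative phosphorylation were mixed, with 20 of 76 higher and 25 lower (19 and 24 adjusted over the list alone). Without POGK replicate 3, 12 were higher, and with library size alone 31 were higher and the median of -0.05 became 0.14. That median lay between -0.12 (without control replicate 3) and -0.0027 (without control replicate 1) with 1 library left out.

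**Figure D3:**
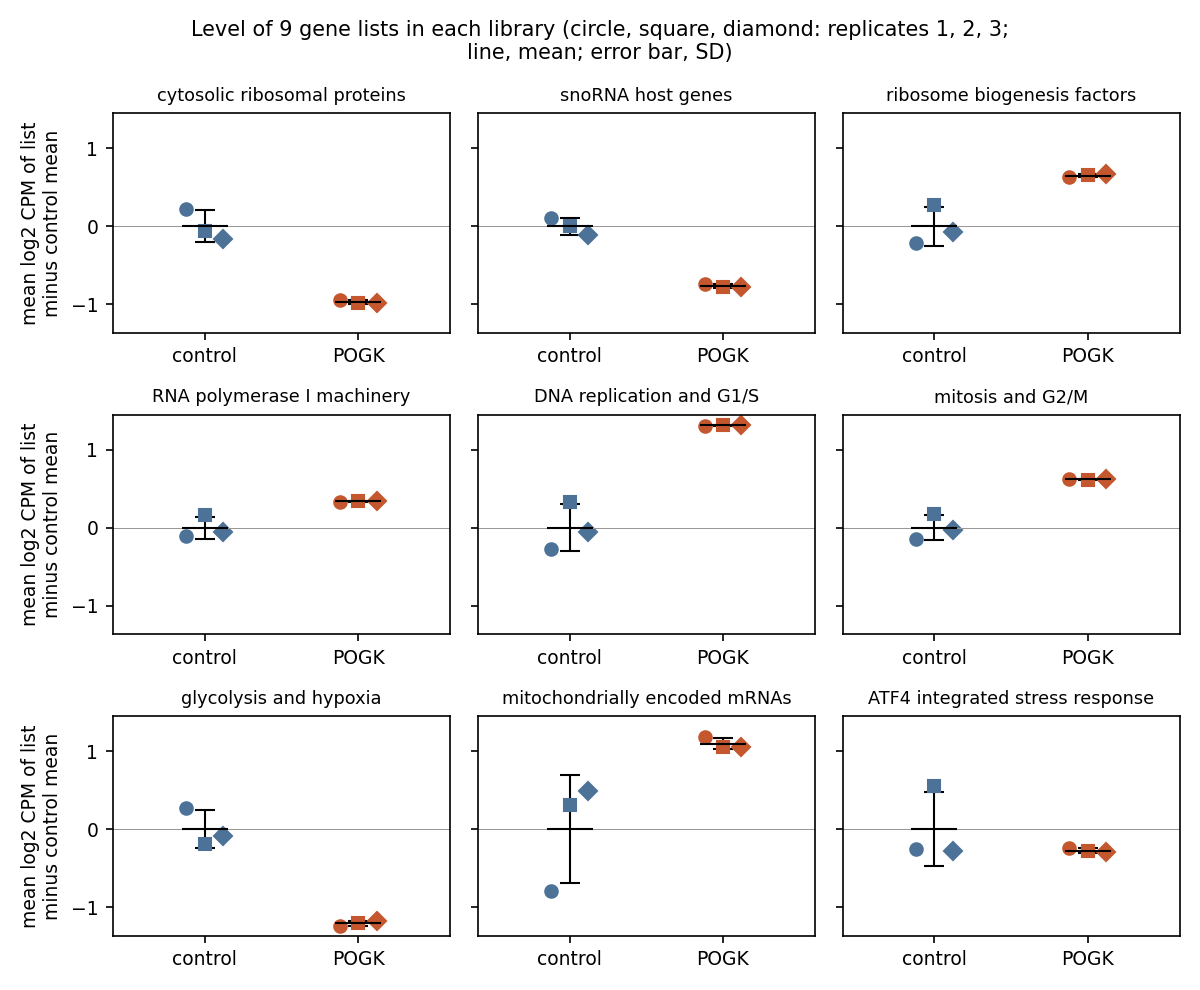
Mean log2 CPM of 9 gene lists in each library, as the difference from the control mean, with the mean and SD of each group. Control replicates spread more than POGK replicates, for example with an SD of 0.30 against 0.01 for DNA replication, and the mean of the mitochondrial mRNAs in control replicate 1 lies at -0.79.

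Extracellular matrix genes fell in 34 of 45 cases and rose in 7, with a median log2 fold change of -0.87. FBLN1, the gene of fibulin, fell from 549 ± 71.9 to 76.6 ± 2.78 CPM, and the collagen genes COL5A1 and COL12A1 fell 2.99-fold and 2.33-fold. The matrix list had a camera adjusted p of 9.28e-05, or an adjusted p = 0.54 with an estimated correlation. Of 27 mesenchymal genes, 17 fell and 8 rose. LOX, a collagen crosslinking enzyme, fell from 483 ± 160 to 28.4 ± 0.78 CPM and the membrane protease gene MMP14 fell 8.39-fold, whereas CDH11, a mesenchymal cadherin, rose from 13.1 ± 0.99 to 80.1 ± 1.51 CPM. VIM, the gene of vimentin, chosen after its values were seen, fell 1.78-fold. Camera called the mesenchymal list at an adjusted p of 0.049, which was lost with DESeq2-style size factors at 0.0501 and without POGK replicate 3 at 0.0527, in a camera range of 0.0156 to 0.543 over all alternatives, and the adjusted p was 0.54 with an estimated correlation.

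The lists of YAP/TEAD targets and of TGF-beta responsive, epithelial, breast stem-like and basal breast genes were not called by camera. YAP/TEAD targets had 13 of 22 genes lower and 6 higher, with falls of 3.03-fold for TGFB2, 2.77-fold for AMOTL2 and 3.48-fold for LATS2. TGF-beta responsive genes had 13 of 21 lower and 5 higher. Epithelial genes had 10 of 19 lower (6 without POGK replicate 1) and 4 higher, and breast stem-like genes 10 of 16 lower and 3 higher (11 and 3 adjusted over the list alone). Basal breast genes had 7 of 16 lower and 5 higher, with a median of -0.20 that vanished with library size alone. Camera adjusted p-values for these 5 lists were 0.14, 0.083, 0.12, 0.083 and 0.41.

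Antigen presentation genes fell in 13 of 19 cases and rose in 4, and leaving out any POGK replicate left 1 that rose and leaving out control replicate 3 left 2. The HLA class I genes HLA-B, HLA-C and HLA-E fell 2.56-fold, 2.32-fold and 2.68-fold, and HLA-B went from 1137 ± 188 to 443 ± 9.41 CPM. HLA genes are similar to each other, so reads may be split between them. Camera gave an adjusted p of 0.0069, or an adjusted p = 0.56 with an estimated correlation. Type I interferon response genes went both ways, with 17 of 43 higher and 19 lower, and their median of -0.03 became 0.17 with library size alone. With 1 library left out it lay between -0.12 (without control replicate 1) and -0.01 (without control replicate 2), and it was -0.06 without control replicate 3 and -0.01 without POGK replicate 1. Inflammatory NF-kB targets had 14 of 28 lower and 2 higher, at a camera adjusted p of 0.12, and 7 were higher without control replicate 2 and 5 with library size alone. The list's mean lay at -0.50 on the log2 scale in control replicate 3, against 0.22 and 0.28 in the other control libraries and -0.44 in POGK cells, and the median of POGK cells minus control replicate 3 was 0.07.

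Cholesterol synthesis genes rose in 15 of 25 cases and fell in 3. HMGCS1, an early enzyme of the sterol pathway, rose from 74.8 ± 14.01 to 312 ± 25.1 CPM, NSDHL rose 2.74-fold and IDI1 rose 2.55-fold. Heat shock chaperones rose in 13 of 23 cases and fell in 4, led by HSP90AA1, which rose from 1015 ± 189 to 3873 ± 30.5 CPM, with STIP1 and HSPE1 up 2.38-fold and 2.39-fold. Camera gave adjusted p-values of 0.0025 for cholesterol synthesis and 0.0091 for chaperones, and the adjusted p was 0.54 with an estimated correlation for both.

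**Figure D4:**
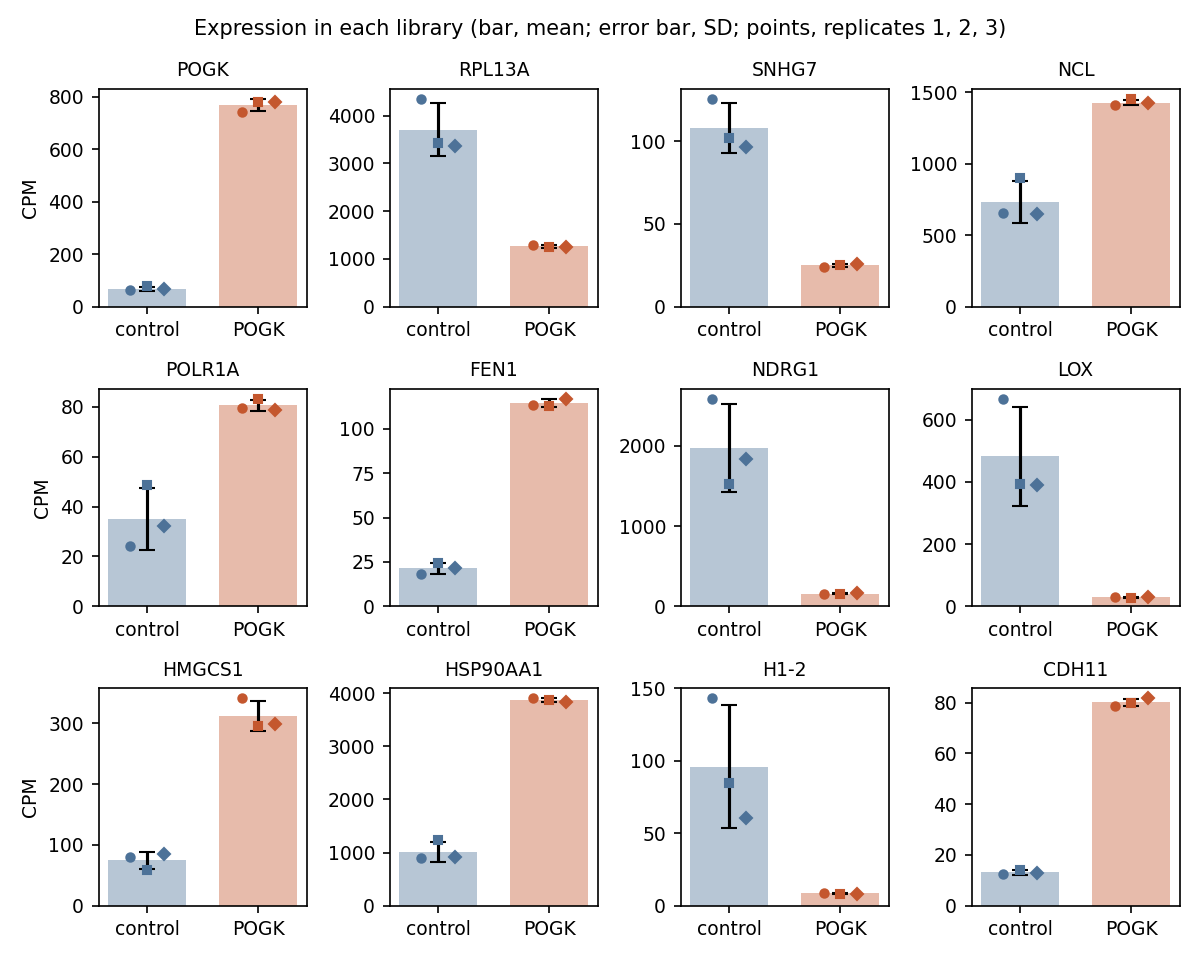
CPM of 12 genes in each library, with bars for group means and error bars for the SD over 3 libraries. POGK rose from 69.0 to 768 CPM and NDRG1 fell from 1978 to 157 CPM, and the control points spread more widely than the POGK points for genes such as NDRG1, with an SD of 549 against 6.08.

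The remaining lists were not called by camera. Genes of the unfolded protein response had 5 of 23 higher and 7 lower (4 and 7 adjusted over the list alone), and their median of -0.02 became 0.18 with library size alone, where 10 were higher and 4 lower. This median was above 0 without control replicate 1, at 0.01, and without POGK replicate 3, at 0.0024, and otherwise lay down to -0.04 (without POGK replicate 1) with 1 library left out. ATF4 stress response genes had 3 of 31 higher and 11 lower (3 and 10 adjusted over the list alone), with a median of -0.14 that became 0.05 with library size alone. Without control replicate 2, in which the list's mean lay at 0.55 on the log2 scale against -0.26 and -0.29 in the other control libraries, 14 were higher and the median was 0.18, whereas it was -0.29 without control replicate 1 and -0.31 without control replicate 3. NRF2 targets had 13 of 27 higher and 6 lower (14 and 6 adjusted over the list alone). Targets of p53 had 7 of 28 higher and 16 lower (8 and 16 adjusted over the list alone), or 4 higher without any 1 of the POGK replicates and 11 with library size alone, at a camera adjusted p of 0.12. Genes of apoptosis and the BCL2 family had 9 of 24 higher and 11 lower (9 and 12 adjusted over the list alone), and their median of -0.11 became 0.08 with library size alone, -0.06 without control replicate 1 and -0.17 without control replicate 3. The list of pogo-derived and other domesticated transposase genes, which is wider than the pogo-like origin of POGK, had 12 of 22 higher and 4 lower. Camera adjusted p-values were 0.89 for the unfolded protein response, 0.20 for ATF4, 0.12 for NRF2, 0.81 for apoptosis and 0.18 for the transposase genes. For the mixed lists of translation factors, oxidative phosphorylation and interferon response they were 0.77, 0.63 and 0.89.

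Markers of other cells were also tested. Luminal breast markers had 4 of 9 higher and 4 lower, leukocyte markers 4 of 7 higher and 2 lower, and endothelial and fibroblast markers 2 of 14 higher and 8 lower, with camera adjusted p-values of 0.78, 0.43 and 0.083. Without POGK replicate 1, 2 luminal and 0 leukocyte markers were lower and 1 endothelial or fibroblast marker was higher. The last count was also 1 without POGK replicate 3, and 1 leukocyte marker was lower without control replicate 2 or 3 or POGK replicate 2. The luminal list had a median of 0.11 and a mean of -0.19, and the median was 0.01 without control replicate 1, 0.04 without control replicate 3 and 0.28 without control replicate 2. Of 5 RNAs chosen as signs of RNA handling, 3 were lower and none higher (1 without control replicate 3), at a camera adjusted p of 0.24. Their mean lay at 0.12, -0.21 and 0.08 on the log2 scale in the control libraries and at -0.24, -0.50 and -0.36 in the POGK libraries.

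Camera called 18 of the 39 lists with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.54, the number at an unadjusted p below 0.05 was also 0 and the median estimated correlation was 0.21. Fry, which does not compare a list with other genes, called 30 lists as moving in one direction and all 39 as changed in either direction. Counts adjusted over the list alone differed from those over all genes in 12 of the 39 lists, by at most 2 genes.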

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

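The tests without mitochondrial genes, with GC and length trends removed and with thinned libraries were chosen only after the results were seen. The counts of called genes stayed within 1.5 times the reported ones under every alternative run. With 1 library left out, 4400 to 5686 genes were higher and 4567 to 5587 lower, and 1230 to 2039 and 1858 to 2289 of them by at least 2-fold. No gene called in the reported comparison was called in the opposite direction under any of these alternatives. The log2 fold change of POGK lay between 3.41 and 3.67. Pairing by replicate number could not be judged. Deviations of same-numbered libraries correlated at 0.09, 0.04 and 0.00 across genes, and control 2 correlated slightly better with POGK 3, at 0.05. The POGK libraries differed little from each other, so such correlations could be small even between paired libraries. With the replicate block 5136 genes were higher and 5103 lower. The block moved the number of mitochondrial mRNAs that rose from 11 to 7.

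The number of lists called by camera was 18, fell to 0 with an estimated correlation, whose median of 0.21 lies above the preset 0.01, and was 30 with the directional fry test, which asks another question. The mesenchymal list lost its call under 7 of the 17 camera alternatives, with camera adjusted p-values from 0.0156 to 0.54, and the mitochondrial mRNAs were not called by fry, at 0.060. Of the named genes CHAC1 and FBL reversed, neither of which had passed the test. FBL went from a log2 fold change of -0.15 to 0.0483 with library size only. CHAC1, a gene chosen after its values were seen, went from -0.63 to 1.02 with limma-voom and 0.47 with the replicate block, and lay between -1.16 and 2.67 with 1 library left out, the highest value without control replicate 2 at an adjusted p of 7.64e-05 (range over alternatives to 0.832). Control replicate 2 held 463 counts of this gene against 8 and 22 in the other control libraries. Of the counts of list members under the alternatives, 1248 stayed within 1.5 times the reported ones, 62 were smaller and 16 larger. Some were smaller because the setting removed list members. Such were mitochondrial mRNAs that rose, at 0 with mitochondrial genes left out, and snoRNA host genes that fell, at 7 with protein-coding genes only. For the others the cause was not tested. Depth limits the genes with group means near 0, whose fold changes rest on a few counts.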

Other observations

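The families below and the tests of 1 divergent control library, of GC and length on the counts and on the ribosome gap, of growth state and of mixed RNA were chosen only after the results they bear on were seen. Of 26 protocadherin genes, which encode adhesion proteins known from neurons, 24 fell and 2 rose, and all 14 tested beta protocadherins fell, with a median log2 fold change of -2.104. PCDHB5 fell from 5.04 ± 0.51 to 1.31 ± 0.22 CPM and PCDHB6 from 3.76 ± 0.67 to 0.44 ± 0.09 CPM. Camera gave an adjusted p of 3.96e-05 for the beta protocadherins over the 7 families tested, and the adjusted p was 0.033 with an estimated correlation. These genes lie side by side and resemble each other, so single members are uncertain. Without control replicate 1 the number of beta protocadherins that fell was also 14.

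Of 14 SLC2A transporter genes, 10 fell (8 without control replicate 1) and 2 rose, with the glucose transporter genes SLC2A1 down from 427 ± 113 to 109 ± 3.76 CPM and SLC2A3 from 1003 ± 265 to 148 ± 6.64 CPM. The camera adjusted p was 0.017, or an adjusted p = 0.29 with an estimated correlation. Of 14 MAGE genes, 9 rose and 2 fell, including MAGEC1 with a rise of 2.40-fold, at a camera adjusted p of 0.012 and an adjusted p of 0.14 with an estimated correlation. Of 18 HLA genes, 14 fell and 1 rose, at a camera adjusted p of 2.56e-04 and an adjusted p of 0.30 with an estimated correlation. Zinc finger genes with ZNF symbols went both ways, with 99 of 448 higher and 155 lower, were not called at a camera adjusted p of 0.20, and had a median of -0.11 that became 0.08 with library size alone. Genes of small nucleolar RNAs were not called either, at 0.20, with 3 of 27 higher and 11 lower (7 without control replicate 1).

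The extent of the difference, 10487 genes or 66.0%, was weighed first. Removing GC and length trends left 10447 called genes, which argues against those trends as the whole cause. With 1 control library left out, the lowest count was 9943. That count cannot decide on 1 divergent control library, because such a library widens the control spread and so lowers the calls. Only 10 splits of the 6 libraries into 3 and 3 exist, so the share of splits cannot fall under 0.05. The real split gave 5202 higher and 5285 lower genes, 1522 and 2017 of them at least 2-fold, and it was the only 1 of the 10 to reach each of these counts. Every other split gave 0 genes by edgeR, limma-voom and DESeq2, with 22 to 80 genes at an unadjusted edgeR p below 0.05. Each of those splits mixes control and POGK libraries, so the group difference widens the spread within its sides. Their 0 calls therefore give no support to the real split.

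For list calls, the real split called 18 lists and the highest other split 22, and 4 of the 10 splits, the real one included, called as many. The lowest other split still called 8 lists, although every other split called 0 genes. Each other split mixes the groups unevenly, so part of the group difference may remain in it. A camera call at the preset correlation therefore does not by itself tie a list to the real grouping. With 10 splits the share cannot fall under 0.05.

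Differences between control libraries were correlated with the group difference. Across 15889 genes, which are not independent replicates, the difference between control 2 and control 1 correlated with the difference between POGK cells and control 3 at r = 0.55 (Spearman 0.62), with no library in common, and the other control pairs gave 0.37 (0.40, control 2 minus control 3) and 0.29 (0.36, control 3 minus control 1). After GC and length trends were removed the largest r was still 0.55, which argues against that bias. RNA of POGK cells in control 2 would have to bring its genes to 23.6% of the way to the POGK level, the median over 764 genes at least 2-fold higher, but 15 genes almost silent in the other controls reached only 3.93% and POGK itself 1.79%. A growth state that varied among control cultures stays open as a candidate explanation. The DNA replication list was 0.58 higher in control 2 than in control 1 on the log2 scale. The 95% range over 10000 random lists of matched expression was -0.08 to 0.14. The other pairs gave 0.45 and 0.24, also above their ranges. Random lists lack the correlation within this list, estimated at 0.63. Passing the range therefore does not single out a growth state. From control 1 to control 2, 16 of the 18 called lists moved the same way as from control 3 to POGK cells. This partly restates the correlation across genes. The 5 RNAs chosen as signs of RNA handling also did so, with medians of -0.40 and -0.47, so a difference in RNA handling stays open too.

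The opposite movement of ribosomal protein and ribosome biogenesis genes opened a gap of 1.68 between the list medians on the log2 scale. It was 1.75 after GC and length trends were removed, which argues against that bias. For the gap between the groups no range over random lists of matched expression was drawn, so the part that goes with expression level is not known. Between control 2 and control 1, the most different pair, the gap was 0.76 against a 95% range of 0.14 to 0.31 for random lists. Part of the gap between the groups may thus follow a state, such as growth or nutrients, that also varies without POGK overexpression. Random lists lack the correlation within these 2 lists, estimated at 0.95 and 0.58, so passing the range does not single out a cause. The gap was 0.53 between control 3 and control 1 and 0.21 between control 2 and control 3, above upper limits of 0.26 and 0.04. In the last pair, however, both medians were higher, at 0.09 for ribosomal proteins and 0.30 for biogenesis factors. Whether the rest comes from POGK or from how the cultures differed cannot be told apart, because no label gives density or passage and each cell population was compared only with the other.

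The POGK libraries resembled each other far more than the controls did, with chi-square values per gene of 1.36 to 2.62 against 22.5 to 49.7. They may be technical repeats, because the labels do not say that they came from separate cultures.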
